A study of Mus musculus with 22 samples.

How the data were processed

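The series holds 22 samples of mouse liver. Messenger RNA was sequenced in 6 of them, chromatin immunoprecipitation (ChIP) was sequenced in 14, and 2 are IgG controls, each pooled over the animals of 1 diet. Livers came from C57BL/6J mice kept on chow or fed a high-fat diet for 16 weeks from the age of 8 weeks, and were taken at 24 weeks after an overnight fast. Groups were read from the sample titles: 3 chow and 3 high-fat-diet libraries each for mRNA, for histone H3 acetylated at lysine 27 (H3K27ac) and for H3 monomethylated at lysine 4 (H3K4me1), and 2 chow libraries for H3 trimethylated at lysine 4 (H3K4me3). Replicate numbers were not used to pair libraries, because the labels do not say that equal numbers stand for 1 animal. The headers of the peak lists carry a different directory code for each diet and the labels name no sequencing batch, so a batch that follows diet cannot be told apart from diet.

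Per the labels, the authors processed mRNA reads with TopHat 1.4.0, HTSeq, DESeq2 1.0.18 and bedtools, and ChIP reads with Bowtie 0.12.7, MACS 1.4.0rc2, bedtools and DESeq2, on the mouse build mm9. The labels do not say which tool made which file. The deposited count files hold raw counts per gene, per union peak and per gene promoter, whole numbers with a different total in each library. The width of a promoter is not stated, and genes and promoters are given by symbol without coordinates. Per the file headers, the peak lists were called on pooled replicates against the IgG control of the same diet at a p-value limit of 1e-06 and kept at a false discovery rate of at most 10 percent. The deposited peak lists also give the tag count of each peak, a score of −10 times the logarithm of its p value, and the fold enrichment over the local background, a ratio. The authors' tables of differential results hold log2 fold changes with their standard errors, p values and adjusted p values from DESeq2, and whether the fold changes were shrunken is not stated. The authors' normalized mRNA signal is a scaled count whose ratio to the raw count differs between genes of 1 library, so it is not 1 size factor per library, and its method is not stated. Printed values were computed from the raw counts, apart from sentences that name the authors' deposited tables.

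Each count table was fitted on its own with edgeR 4.0.16 in R 4.3.3. Features passed filterByExpr by diet, libraries were scaled with TMM factors, and the diets were compared with the quasi-likelihood F test, two-sided, with diet as the only term. Adjusted p values are Benjamini-Hochberg values over the features tested in 1 table, and the threshold was 0.05. In the text, rose and fell are used of features past this threshold, as high-fat diet against chow. Fold changes and log2 fold changes come from the fit, with the standard error (SE) of the log2 value. Levels are CPM, counts divided by the TMM-scaled library total and multiplied by 1e+06, with the standard deviation (SD) over libraries (n = 3 per diet). A single measure compared between 3 and 3 libraries can reach an exact permutation p of 0.1 at the lowest, so no such test was used for single genes. Total counts ran from 19016275 to 45741794 for mRNA, from 2037101 to 5772962 for H3K27ac in peaks, from 1967613 to 4964403 for H3K27ac at promoters and from 5487592 to 7380206 for H3K4me1. A ratio of summed counts of a gene with 1 to 3 counts in 1 diet carries a 95% interval (conditional binomial, Clopper-Pearson). Intervals cover counting error of the summed counts only and leave out the spread between libraries. Reads carry no molecular identifiers, so copies of 1 molecule cannot be told from separate molecules.

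The fits were tested on simulated data at these depths. In each table changes were planted in 200 features with an average log2 CPM over 2. Features were drawn independently, without shifts shared by a whole library. The shares below thus do not cover features with fewer counts, and real data may give more false calls. For mRNA, 89% of genes planted with a 2-fold change and 99% of those with a 4-fold change passed, and 3.59% of calls were false. For H3K27ac peaks, 88% of regions planted with a log2 change of 0.5 passed, 99% at a log2 change of 1, and 9.22% of calls were false. For promoters the shares were 39% and 85%, with 3.12% false. For H3K4me1 peaks they were 68% and 100%, with 5.08% false.

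Before the data were examined, 39 gene lists with 597 genes were fixed. They cover liver pathways, responses, sex-biased genes and markers of other cell types. Lists with at least 3 tested members were compared with the other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and beside it with an estimated correlation, adjusted over the lists. Fry tested whether the members move, on balance, in 1 direction. Members past the threshold were counted with the adjustment over all genes tested and with the adjustment over the list alone. For promoters, 1 promoter per symbol was used, the one with the highest mean count. Near-identical genes (major urinary proteins, trypsins, Cyp2b, Cyp4a and Saa genes) can share reads, so family sums were computed as well.

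Genes named in the text were taken by a rule fixed before the data were examined. For mRNA it takes the 12 genes with the largest and the 12 with the smallest log2 fold change among those past the threshold with an average log2 CPM of at least 1 and with no overlap between the libraries of the diets. In each list it adds up to 4 members with the smallest p. For promoters and peaks it takes the 10 with the smallest p among those that rose and the 10 among those that fell, with no overlap, and the promoters of the named mRNA genes. Genes named outside this rule are said to have been chosen after their values were seen.

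Promoter acetylation was compared with mRNA over genes tested in both assays, by the median promoter log2 fold change of the raised and the lowered genes, by camera and fry on the promoter fit (adjusted over these 2 sets, an adjustment chosen after the values were seen), by correlations across genes, and by Fisher's exact test, two-sided. Camera sets a gene set against all 20891 tested promoters, while fry tests it against no change. Genes and peaks are not independent replicates, so correlations across them are given without p. Peak overlaps (GenomicRanges 1.54.1) counted from 1 shared base. Shares of peaks carry 95% exact (Clopper-Pearson) intervals.

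Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no count filter, a filter of at least 50 counts in at least 3 libraries, the replicate number as a block, each library left out in turn, total counts without TMM factors and cyclic loess for the ChIP tables, overlap of at least 50% of a peak, peaks with a false discovery rate of at most 1 percent, and peak lists of equal length. Alternatives chosen after seeing the data were total counts without TMM factors for mRNA, the mean log2 CPM of the pancreas list as a covariate, limma on the authors' normalized signal, cyclic loess for mRNA and for the mRNA and promoter lists, 1 of each set of promoters with identical counts for the promoter lists, the genes of both assays in place of all promoters as the background of the raised and lowered sets, each library left out for the correlation of the marks and for the H3K4me3 overlap, the family sums, and all alternatives for genes named outside the rule. Where a setting leaves 1 diet with 2 libraries, the fit pools the spread over both diets.

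The IgG libraries have no file of their own and were used only through the authors' peak lists. Interval files that repeat the peak lists were not used, since every start, end and score in them equals the value in the list. The planned comparison of peaks near changed genes was left out, because no transcription start sites on mm9 were available, and no gene is assigned to a peak.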

Results

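The study measured mRNA and histone marks in livers of C57BL/6J mice that ate chow or, for 16 weeks, a high-fat diet. For each diet there were 3 mRNA libraries, 3 H3K27ac libraries (a mark of active promoters and enhancers) and 3 H3K4me1 libraries (a mark of enhancers). Chow livers also had 2 H3K4me3 libraries (a mark of promoters), which the high-fat diet lacks. In chow replicates 1 to 3, 45741794, 19131339 and 19016275 mRNA counts fell on 23227 genes, and in high-fat-diet replicates 1 to 3 there were 22513186, 23948777 and 20977959. H3K27ac totals over 11235 union peaks were 4831139, 2729808 and 5772962 for chow and 2037101, 4374345 and 3923847 for the high-fat diet. Over 23167 gene promoters they were 4265510, 2376133 and 4964403 for chow, and 1967613, 3788577 and 3544273 for the high-fat diet. H3K4me1 totals over 16834 union peaks were 6716264, 7380206 and 5969153 for chow, and 5487592, 6931725 and 6492247 for the high-fat diet. Genes and promoters are identified by symbol, and peaks by their position on mm9.

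The series concerns hepatic insulin resistance brought on by diet, and the mRNA comparison asks which liver genes differ between the diets. Interferon-induced genes were higher on the high-fat diet as a list, the only list that also passed with an estimated correlation (camera adjusted p = 0.0451). Lists of acute-phase, clock, and urea and amino acid genes and of targets of the lipid-sensing receptor PPARα passed with the preset correlation but not with the estimated one (adjusted p = 0.771 for the acute phase, adjusted p = 0.454 for the others). Fat synthesis genes moved in both directions, with 8 raised, 4 lowered and 5 not past the threshold, and their list did not pass with the estimated correlation either (adjusted p = 0.771). Fry passed the interferon list (adjusted p = 0.000519), the clock and urea lists (adjusted p = 0.00605 each) and PPARα targets (adjusted p = 0.00878). It did not pass acute-phase or fatty acid synthesis genes (adjusted p = 0.0616 each). By fry gluconeogenesis, sterol uptake, glycolysis and triglyceride synthesis also passed (adjusted p = 0.0116 each). So did cell cycle (adjusted p = 0.0167) and the 6 of 14 female-biased genes that passed the count filter (adjusted p = 0.03). Thrsp, a nuclear protein of lipogenic tissues, rose 38.4-fold (log2 5.26, SE 0.275). Ehhadh, an enzyme of peroxisomal fatty acid oxidation, was 8.30-fold lower (log2 −3.05, SE 0.171), and Asns, which makes asparagine, was 19.1-fold lower (log2 −4.26, SE 0.429). Adjusted p values of these 3 genes ran from 3.79e-05 to 0.000305 (edgeR, n = 3 per diet).

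Of 12909 genes tested, 4590 passed, 2319 higher and 2271 lower on the high-fat diet, and 928 of these differed over 2-fold, 622 higher and 306 lower. The libraries of the diets did not overlap in 6528 genes (50.6%, against 10% by chance). The first principal component held 66.9% of the variance and parted the diets. Without chow replicate 2, 2899 genes passed. With the mean of the pancreas-list genes as a covariate, which itself differs between the diets, 874 passed, 867 of them also among the 4590. With total counts in place of TMM factors the median log2 fold change of all genes was 0.10 in place of 0.02, and 2805 genes were higher and 1646 lower. With total counts 2 fatty acid synthesis, 3 insulin signaling and 3 glutathione genes fell in place of 4, 5 and 5, and 8 drug-metabolising P450 and 12 unfolded protein response genes rose in place of 5 and 8. Of all genes, 4788 pass in the authors' deposited table, 2478 higher and 2310 lower, and 3365 of these also passed here, all in the same direction.

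The rule named 12 genes with the largest increases. Cyp2b9 and Cyp2b13 are cytochromes P450 known to be higher in female mouse liver. Cyp2b9 went from 1.10 CPM (SD 1.06) on chow to 353 CPM (SD 145), a log2 difference of 8.38 that was 9.11 without chow replicate 2. In mRNA Cyp2b13 had 1 count in the 3 chow libraries and 1992 in the others, a ratio of 2344 (95% counting interval 420 to 92620). Of the 1992 counts, 1663 came from high-fat-diet replicate 3, and the 1 chow count came from replicate 2. Summed over Cyp2b genes, 5.83 CPM (SD 0.679) on chow became 390 CPM (SD 189). Hao2, a peroxisomal hydroxyacid oxidase, had 5 counts in the chow libraries, 4 of them in replicate 1, and 268 in the others, a log2 difference of 5.88. Lcn2, which binds bacterial siderophores, rose 15.1-fold, Saa2, a serum amyloid A, 13.8-fold, and Gbp10, a guanylate-binding protein, 13.9-fold. The non-coding C730036E19Rik rose 24.2-fold and the transcribed pseudogene 9030619P08Rik 14.3-fold. Car3, a carbonic anhydrase, rose by a log2 of 3.75 (4.34 without chow replicate 1), and Slc22a27, of the organic anion transporter family, by 4.25 (3.53 without chow replicate 1, 3.66 without high-fat-diet replicate 3). Among the 12 largest decreases, the non-coding 3930402G23Rik fell by 5.68 on the log2 scale (6.29 without high-fat-diet replicate 1), Gm15441 was 20.2-fold lower and the protein-coding E030018B13Rik had a log2 fold change of −4.32. The other 8 decreases, apart from Asns, were enzymes and granule proteins of exocrine cells, described with the pancreas list.

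**Figure D1:**
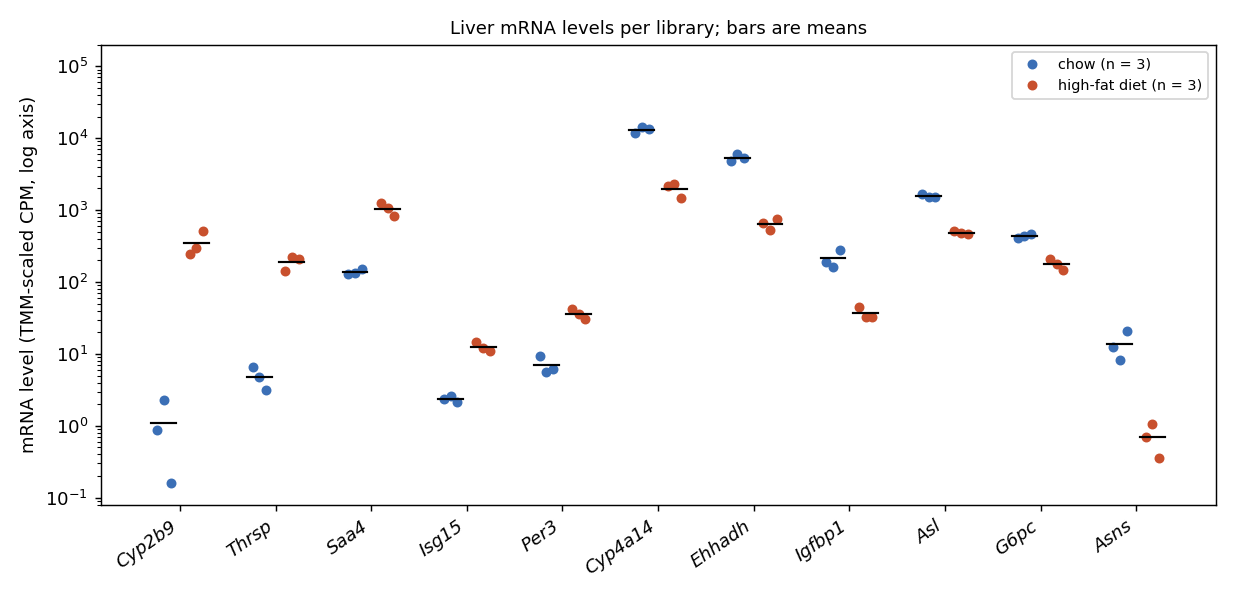
Levels of 11 named genes in each mRNA library (TMM-scaled CPM, log axis), chow in blue and high-fat diet in orange, with bars at the mean of 3 libraries. For each of the 11 genes the 3 libraries of one diet lie apart from the 3 of the other, and Thrsp goes from a mean of 4.83 to 192 CPM.

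Lipid synthesis genes moved in both directions. Of 17 fatty acid synthesis genes, 8 rose, 4 fell and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0464; adjusted p = 0.771 with an estimated correlation). Srebf1, the transcription factor that drives lipogenesis, rose 4.51-fold (log2 2.17, SE 0.221) and Fasn, fatty acid synthase, rose 2.45-fold. Elovl5, which lengthens polyunsaturated fatty acids, was 2.22-fold lower. Of 9 triglyceride synthesis genes, 3 rose, 2 fell and 4 did not pass, as with the adjustment over the list alone. Camera did not call the list (adjusted p = 0.375), while fry called it as higher (adjusted p = 0.0116). Its median log2 fold change was −0.07 and its mean 0.40, its test pointed up, and the median turned to 0.01 with total counts. Dgat2 rose 2.44-fold, Lpin1 3.16-fold, and Dgat1, the other enzyme of the last step, was 1.33-fold lower. Of 13 lipid droplet genes, 5 rose, 3 fell and 5 did not pass, as over the list alone (camera adjusted p = 0.375). Plin4 rose 2.08-fold, Fitm1 2.50-fold and Pparg, a regulator of fat storage, 1.75-fold, while Pnpla2, a triglyceride lipase, was 1.62-fold lower. Cd36, a fatty acid importer, rose 2.58-fold and the droplet coat gene Plin2 was 1.66-fold lower, both chosen after their values were seen. The call of the fatty acid synthesis list ended without chow replicate 2 (adjusted p = 0.0517), without high-fat-diet replicate 3 (adjusted p = 0.075) and with cyclic loess (adjusted p = 0.0813), a setting chosen for mRNA after the data were seen.

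More sterol genes rose than fell. Of 19 cholesterol synthesis genes, 7 rose, 1 fell and 11 did not pass, as over the list alone (camera adjusted p = 0.0492; adjusted p = 0.893 with an estimated correlation). Acat2 rose 1.59-fold and Mvd, of the mevalonate pathway, 4.48-fold. Of 12 sterol uptake and efflux genes, 7 rose, 1 fell and 4 did not pass, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0492; adjusted p = 0.522 with an estimated correlation). Abcg8, a sterol exporter, rose 1.69-fold, and Insig2, which holds back sterol regulatory proteins, was 3.05-fold lower. Cholesterol synthesis ended as a call without chow replicate 2 (adjusted p = 0.0517), chow replicate 3 (adjusted p = 0.0713), high-fat-diet replicate 1 (adjusted p = 0.077) and high-fat-diet replicate 2 (adjusted p = 0.29). Sterol uptake ended without chow replicates 1, 2 or 3 (adjusted p = 0.0749, adjusted p = 0.0581 and adjusted p = 0.0601) and without high-fat-diet replicate 1 (adjusted p = 0.077).

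More fatty acid oxidation genes fell than rose. Of 20 peroxisomal, microsomal and other PPARα targets, 1 rose, 10 fell and 9 did not pass, and 1 rose and 12 fell adjusted over the list alone (camera adjusted p = 1.93e-09; adjusted p = 0.454 with an estimated correlation). Besides Ehhadh, Cyp4a14 was 6.70-fold lower (log2 −2.74, SE 0.209), Cyp4a10 3.76-fold lower and Acot1 3.39-fold lower. The 4 near-identical Cyp4a genes of the list summed to 19700 CPM (SD 1800) on chow and 3802 CPM (SD 612) on the high-fat diet, 5.18-fold lower. Pdk4, which holds back glucose oxidation, had a log2 fold change of −1.97 (SE 0.215, adjusted p = 0.000433) and the hormone gene Fgf21 one of −1.22 (adjusted p = 0.00703). Vnn1, a pantetheinase, was the member that rose, by a log2 of 0.56 (adjusted p = 0.0181, and adjusted p = 0.0504 without chow replicate 1). These 3 genes were chosen after their values were seen. Of 19 genes of mitochondrial oxidation and ketone synthesis, 2 rose, 9 fell and 8 did not pass, and 3 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.0262; adjusted p = 0.856 with an estimated correlation). Etfdh was 1.75-fold lower and Hadhb 1.63-fold lower, while Bdh1, a ketone body enzyme, rose by a log2 of 0.59 and Hadh by 0.58. The mitochondrial list ended as a call without chow replicate 1 (adjusted p = 0.0544) and without high-fat-diet replicate 3 (adjusted p = 0.075).

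Genes of glucose handling and insulin signaling moved in both directions within each list. Of 10 gluconeogenesis genes, 2 rose, 6 fell and 2 did not pass, and 2 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.0417; adjusted p = 0.522 with an estimated correlation). G6pc, the last step of glucose output, was 2.48-fold lower (log2 −1.31, SE 0.125), Fbp1 1.37-fold lower and the coactivator gene Ppargc1a 1.46-fold lower. Pck1, the first committed enzyme, had a log2 fold change of −0.32 (adjusted p = 0.218) and was chosen after its value was seen. This list ended as a call without chow replicate 1 (adjusted p = 0.0943) and without high-fat-diet replicate 2 (adjusted p = 0.0538). Of 13 glycolysis genes, 3 rose, 3 fell and 7 did not pass, and 5 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0682). Fry called this list as higher (adjusted p = 0.0116). Pklr, the liver pyruvate kinase, rose 3.12-fold and Pfkl 2.06-fold, and Aldoa was 1.37-fold lower. By camera the glycolysis list passed without chow replicate 2 (adjusted p = 0.0192), high-fat-diet replicate 1 (adjusted p = 0.0404) or high-fat-diet replicate 2 (adjusted p = 0.0435). Of 19 insulin signaling genes, 5 rose, 5 fell and 9 did not pass, as over the list alone (camera adjusted p = 0.977). Their median log2 fold change was 0.01, and −0.002 with DESeq2 size factors and −0.04 with cyclic loess, their mean −0.03, camera pointed down and fry up. Igfbp1, a secreted protein whose mRNA insulin lowers, was 5.81-fold lower (log2 −2.54, SE 0.22). Pik3r1, a regulatory subunit of the insulin-activated lipid kinase, rose 1.82-fold, Foxo3 2.48-fold and the phosphatase Ptprf 1.77-fold. Irs2, an adaptor of the insulin receptor, was lower by a log2 of −0.92 (SE 0.13, adjusted p = 0.00129), Foxo1 higher by 0.63 (adjusted p = 0.000876), and the receptor Insr had −0.11 (adjusted p = 0.32). These 3 were chosen after their values were seen.

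Of 15 genes of the urea cycle and amino acid breakdown, 1 rose, 10 fell and 4 did not pass, as over the list alone, with a median log2 fold change of −0.85 (camera adjusted p = 5.29e-08; adjusted p = 0.454 with an estimated correlation). Asl and Arg1, the last steps of the urea cycle, had log2 fold changes of −1.69 (SE 0.1) and −1.27 (SE 0.101), and Hgd, of tyrosine breakdown, was 2.12-fold lower. Glul, glutamine synthetase, rose by a log2 of 0.58 (adjusted p = 0.0159), a call that ended without chow replicate 2 or 3 (highest adjusted p = 0.0732), and was chosen after its value was seen. Of 15 apolipoprotein and lipoprotein assembly genes, 4 rose, 3 fell and 8 did not pass, and 6 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.864). The median log2 fold change was −0.0005, the mean 0.001, the test pointed down, and the median was 0.07 with total counts and 0.02 with cyclic loess. Mttp, which loads lipid onto apolipoprotein B, was 1.48-fold lower and Apom 1.57-fold lower. Of 13 bile acid synthesis genes, 1 rose, 6 fell and 6 did not pass, as over the list alone (camera adjusted p = 0.131). Cyp8b1, the sterol 12-alpha-hydroxylase, was 3.07-fold lower, Baat 1.56-fold lower, and Akr1d1 rose 2.12-fold. Of 13 bile acid transport genes, 2 rose, 3 fell and 8 did not pass, as over the list alone (camera adjusted p = 0.697). Slco2b1 rose 1.71-fold, and Abcb4, the phospholipid exporter, was 1.79-fold lower. Of 28 respiratory chain genes, 1 rose, 8 fell and 19 did not pass, as over the list alone (camera adjusted p = 0.105, and adjusted p = 0.0127 without high-fat-diet replicate 1). Sdhd was 1.43-fold lower and Ndufs1 1.29-fold lower.

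Of 23 drug-metabolising cytochromes P450, 5 rose, 3 fell and 15 did not pass, as over the list alone (camera adjusted p = 0.809), while 8 rose with cyclic loess. Cyp2a5 rose 2.40-fold and Cyp3a25 was 2.63-fold lower. Of 18 glutathione and NRF2 target genes, 2 rose, 5 fell and 11 did not pass, as over the list alone (camera adjusted p = 0.754). The median log2 fold change was 0.12 while the test pointed down, and Gsta3 rose 2.31-fold while Gstp1, another glutathione transferase, was 2.71-fold lower.

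Genes that differ between the sexes in mouse liver changed in opposite directions by list. Of 6 tested female-biased genes, 4 rose, none fell and 2 did not pass, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000197; adjusted p = 0.581 with an estimated correlation, and adjusted p = 0.0525 with cyclic loess). Of the 14 members of the list only these 6 passed the count filter. Cyp2b13 and Hao2, with 1 and 5 chow counts, passed it through the high-fat-diet libraries. Members with so few chow counts could enter only by rising, so the filter partly sets the upward calls of this list. Besides the genes above, Cyp2a4 rose 4.09-fold (log2 2.03, SE 0.207). Of 12 male-biased genes, 2 rose, 7 fell and 3 did not pass, and 3 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.000809; adjusted p = 0.771 with an estimated correlation). Cyp4a12a and Cyp4a12b, fatty acid hydroxylases, summed to 395 CPM (SD 9.75) on chow and 73.6 CPM (SD 19.8) on the high-fat diet, and Elovl3 was 2.48-fold lower. Serpina12, a secreted serpin chosen after its value was seen, rose by a log2 of 0.87 (adjusted p = 0.0151, and adjusted p = 0.0667 without chow replicate 2). Of 19 major urinary protein genes, 2 rose, 6 fell and 11 did not pass, as over the list alone, with camera adjusted p = 0.131. Without high-fat-diet replicate 1 that list passed (adjusted p = 1.06e-08). Mup20 was 2.18-fold lower and Mup5 rose 4.34-fold. Reads of 20 near-identical urinary protein genes, Mup20 among them, summed to 32980 CPM (SD 2970) on chow and 16420 CPM (SD 8090) on the high-fat diet.

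Of 21 acute-phase genes, 8 rose, 1 fell and 12 did not pass, as over the list alone (camera adjusted p = 5.01e-05; adjusted p = 0.771 with an estimated correlation). Besides Saa2 and Lcn2, Saa4 rose 7.55-fold (log2 2.92, SE 0.165) and Orm3 5.36-fold. Saa1 rose by a log2 of 3.08 (adjusted p = 0.000286) and Hamp, which encodes the iron hormone hepcidin, had −1.12 (adjusted p = 0.00386), both chosen after their values were seen. The near-identical Saa1 and Saa2 together went from 26.9 CPM (SD 6.42) to 252 CPM (SD 85.9). Of 19 unfolded protein response genes, 8 rose, 1 fell and 10 did not pass, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0443; adjusted p = 0.857 with an estimated correlation). Edem1, of protein degradation, rose by a log2 of 0.68, the chaperone Hyou1 2.32-fold and Chac1, a glutathione-degrading enzyme, 6.26-fold, while Asns was the member that fell. The list ended as a call without chow replicate 1 (adjusted p = 0.118), chow replicate 3 (adjusted p = 0.0601) or high-fat-diet replicate 1 (adjusted p = 0.077).

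Interferon-stimulated genes rose as a group. Of 23 genes, 22 rose, none fell and 1 did not pass, as over the list alone, with a median log2 fold change of 1.38, and this was the 1 mRNA list of 16 that also passed with an estimated correlation (camera adjusted p = 5.69e-22; adjusted p = 0.0451 with an estimated correlation). Isg15 rose 5.32-fold (log2 2.41, SE 0.161), Ifit1 4.28-fold and Usp18 3.67-fold. Stat2, a transcription factor of the interferon response, did not pass (log2 0.26, adjusted p = 0.221), apart from the fit without high-fat-diet replicate 3, and was chosen after its value was seen. Of 13 cytokine, chemokine and adhesion genes, 4 rose, 1 fell and 8 did not pass, as over the list alone (camera adjusted p = 0.0492; adjusted p = 0.771 with an estimated correlation). The chemokines Cxcl9 and Cxcl10 rose 3.77-fold and 4.24-fold, and Ccl2 5.39-fold. This list ended as a call without chow replicate 1 (adjusted p = 0.195), high-fat-diet replicate 2 (adjusted p = 0.101) or high-fat-diet replicate 3 (adjusted p = 0.075), and with cyclic loess (adjusted p = 0.0679). Of 15 cell cycle genes, 5 rose, none fell and 10 did not pass, as over the list alone (camera adjusted p = 0.0492; adjusted p = 0.548 with an estimated correlation). E2f1 rose 2.55-fold and the replication helicase gene Mcm2 1.70-fold. The cell cycle list ended as a call without chow replicates 1 or 2 (adjusted p = 0.0771 and adjusted p = 0.0517) and without high-fat-diet replicates 2 or 3 (adjusted p = 0.101 and adjusted p = 0.104). With cyclic loess 3 cell cycle genes rose and the list did not pass (adjusted p = 0.0558). Of 20 matrix genes, 6 rose, 1 fell and 13 did not pass, as over the list alone (camera adjusted p = 0.0646, and adjusted p = 0.000238 without high-fat-diet replicate 1). Fn1, fibronectin, rose 1.69-fold.

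Markers of other cell types were measured beside these groups. Of 7 class II antigen presentation genes, 5 rose, none fell and 2 did not pass, as over the list alone (camera adjusted p = 0.0587), and the list passed without chow replicate 3 (adjusted p = 0.0362) or high-fat-diet replicate 1 (adjusted p = 0.00421). With cyclic loess 3 of the 7 rose and the list passed (adjusted p = 0.041). Cd74 had a log2 fold change of 0.72 (adjusted p = 0.0221), a call that ended without chow replicate 1 or 2 or high-fat-diet replicate 2 (highest adjusted p = 0.0894). Of 8 markers of infiltrating macrophages, 6 rose, 1 fell and 1 did not pass, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0943). Without high-fat-diet replicate 1 or 2 this list passed (adjusted p = 0.0274 and adjusted p = 0.0407), and with cyclic loess 3 rose and 1 fell, with a median log2 fold change of 1.13 in place of 1.43 (adjusted p = 0.0813). Mmp12, a macrophage elastase, rose by a log2 of 3.51, and by 2.37 without high-fat-diet replicate 3. Of 15 Kupffer cell and macrophage markers, 2 rose, none fell and 13 did not pass, as over the list alone (camera adjusted p = 0.282). That list passed without chow replicate 3 (adjusted p = 0.00614) or high-fat-diet replicate 1 (adjusted p = 0.0404), and Mpeg1 rose 2.21-fold. None of 7 lymphocyte markers passed (edgeR, camera adjusted p = 0.642) and none of 3 neutrophil markers did (camera adjusted p = 0.809). Of 14 endothelial markers, 2 rose and 12 did not pass, and none rose adjusted over the list alone (camera adjusted p = 0.276, and adjusted p = 0.00634 without high-fat-diet replicate 1). Of 10 stellate cell markers, 1 rose and 9 did not pass, as over the list alone (camera adjusted p = 0.593), and of 6 bile duct markers 1 fell and 5 did not pass, as over the list alone (camera adjusted p = 0.593). Of 12 hepatocyte markers, 1 rose, 2 fell and 9 did not pass, as over the list alone (camera adjusted p = 0.538), with a median log2 fold change of −0.06 that was 0.01 with total counts. With total counts 2 rose and 2 fell, and with cyclic loess 3 rose and 2 fell. Cps1, a urea cycle enzyme on this list, was 2.29-fold lower. Adipocyte and erythroid lists had 2 and 1 tested members, too few to test as lists, and all of them rose, as over the lists alone. Among these Cfd, an adipocyte complement protease, rose by a log2 of 3.41 (4.23 without chow replicate 1).

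**Figure D2:**
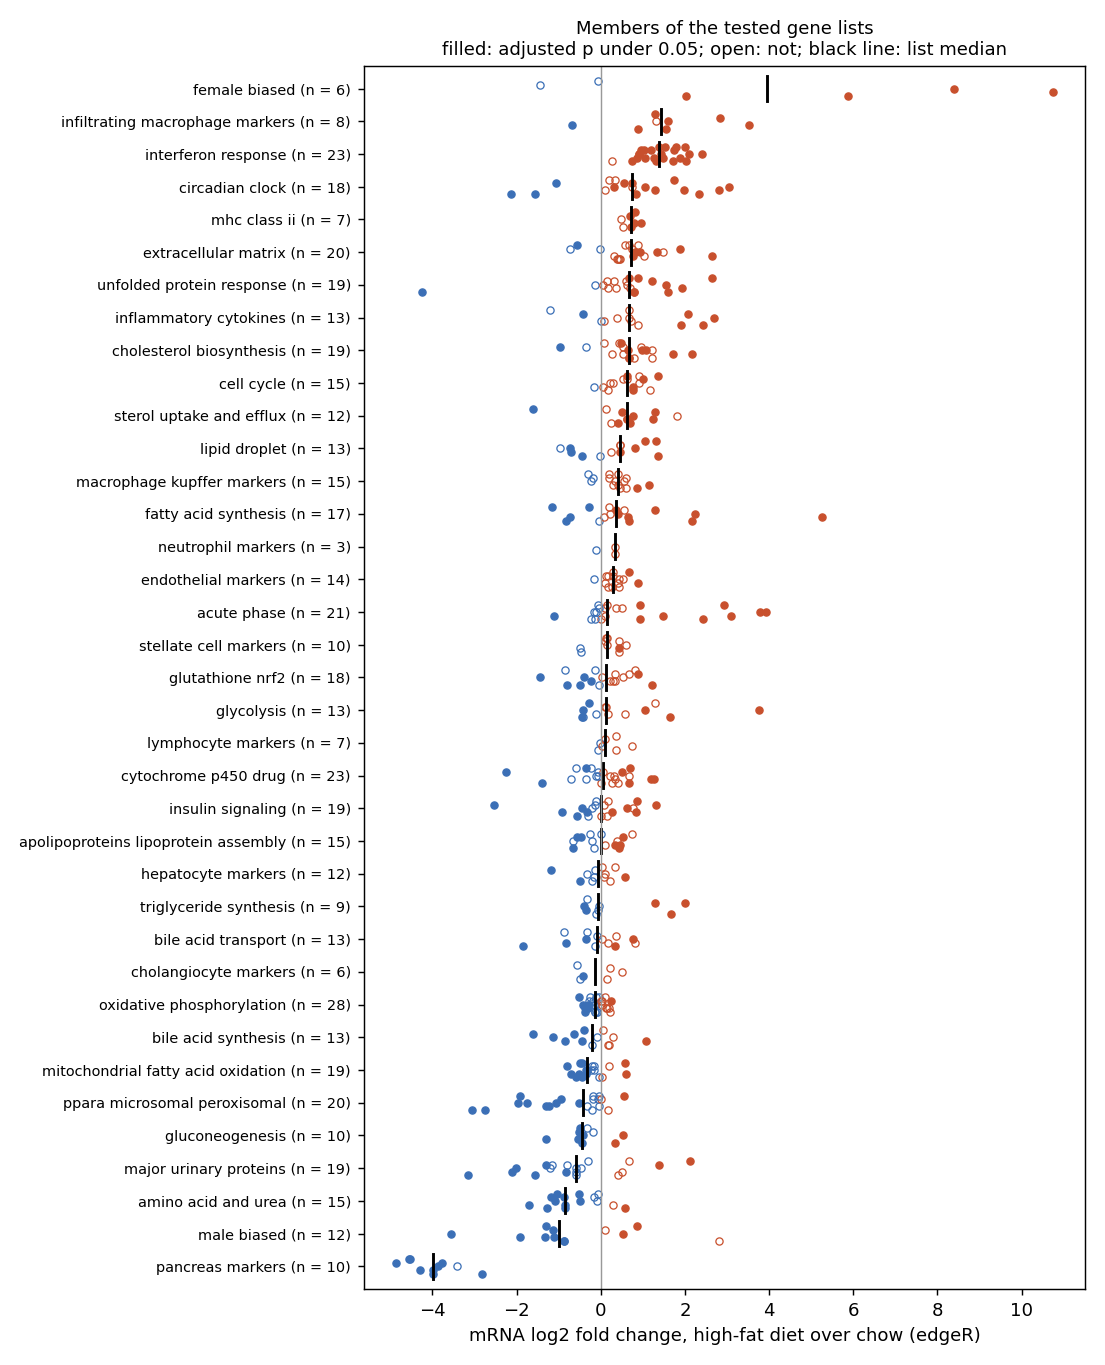
Log2 fold change in mRNA, high-fat diet over chow, of each tested member of the gene lists, with filled points past the threshold, open points not, and a black line at the list median. The interferon list lies to the right of 0 with a median of 1.38, and the urea and amino acid list to its left with a median of −0.85.

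Clock genes differed between the diets. Of 18 genes, 11 rose, 3 fell and 4 did not pass, as over the list alone, with a median log2 fold change of 0.74 (camera adjusted p = 9.36e-07; adjusted p = 0.454 with an estimated correlation). The repressor genes Per2 and Per3 rose 3.31-fold and 5.05-fold, Bhlhe40 3.95-fold (log2 1.98, SE 0.0871) and Gm129, also called Ciart, 8.23-fold. Among genes chosen after their values were seen, the activator genes Arntl, Npas2 and Clock had log2 fold changes of −2.14, −1.55 and −1.06, and the output genes Dbp and Tef 2.82 and 1.04. Adjusted p values of these 5 genes ran from 0.00035 to 0.00632. Labels give no clock time of collection.

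Pancreatic enzymes were the largest group among the 12 strongest decreases. Of 10 tested exocrine pancreas genes none rose, 9 fell and 1 did not pass, and 10 fell adjusted over the list alone, with a median log2 fold change of −3.995 (camera adjusted p = 0.00275; adjusted p = 0.771 with an estimated correlation). Without high-fat-diet replicate 2 the median was −8.97, without chow replicate 1 it was −3.13, and with cyclic loess it was −6.28 and 8 fell. With total counts 6 fell. Summed, these genes reached 1893, 826 and 312 CPM in chow replicates 1 to 3 and 22.7, 177 and 10.1 CPM in high-fat-diet replicates 1 to 3, so libraries of the same diet differed several-fold. The trypsin genes Try4 and Try5, which share reads, summed to 96.5 CPM (SD 76.6) on chow and 3.51 CPM (SD 5.85) on the high-fat diet. Their log2 ratio of −4.78 became −9.48 without high-fat-diet replicate 2 and −3.99 without chow replicate 1. Cpb1 and Cela2a, a carboxypeptidase and an elastase, had log2 fold changes of −4.55 and −4.30, calls that ended without chow replicate 1 or 2 (highest adjusted p = 0.0542 and adjusted p = 0.0699). Without high-fat-diet replicate 2 they had −9.77 and −8.07, and without chow replicate 1 −3.82 and −3.39. Of genes outside the list but named by the rule, the zymogen granule protein gene Gp2 had a log2 fold change of −5.18, with 20 of its 23 high-fat-diet counts in replicate 2. The lipase-related Pnliprp2 had one of −4.92 (−4.15 without chow replicate 1), with all 26 of its high-fat-diet counts in replicate 2, and did not pass with the DESeq2 Wald test (adjusted p = 0.069). Klk1, a kallikrein, had −4.80 (−6.87 without high-fat-diet replicate 2, −4.17 without chow replicate 1).

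**Figure D3:**
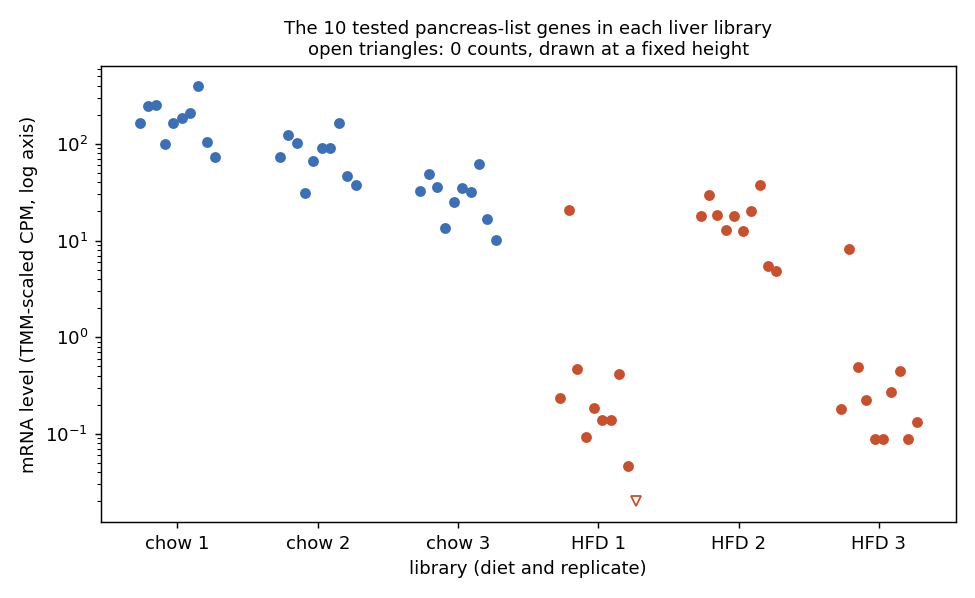
Levels of the 10 tested pancreas-list genes in each mRNA library (TMM-scaled CPM, log axis), chow in blue and high-fat diet in orange, with open triangles for 0 counts. The summed level is 1893 CPM in chow replicate 1 and 10.1 CPM in high-fat-diet replicate 3.

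The H3K27ac comparison asks where the mark of active promoters and enhancers differs between the diets. The peak at chromosome 1, 94727530 to 94733817, rose from 71.4 CPM (SD 9.01) to 129 CPM (SD 6.84), a log2 difference of 0.84 (SE 0.0946, adjusted p = 4.21e-05). The peak at chromosome 9, 21470393 to 21480546, rose by the same log2 amount of 0.84 (SE 0.0944). On chromosome 17 neighbouring peaks fell: 14335677 to 14341859 by 0.71 (SE 0.098) and 14305459 to 14314744 by 0.78 (SE 0.113) on the log2 scale. Of 11235 union peaks 215 passed, 135 risen and 80 fallen, none over 2-fold, with a median absolute log2 fold change of 0.46. The diets did not overlap in 2170 peaks (19.3%, against 10% by chance), and 1577 peaks had an unadjusted p below 0.05. The first principal component of these peaks held 45.7% of the variance. High-fat-diet replicate 1 lay at 20.62 on it, replicates 2 and 3 at −1.761 and 3.118, and the chow libraries from −8.326 to −5.472. Without chow replicate 1, 46 peaks passed. The other counts beyond 1.5-fold were 111 without chow replicate 2, 44 without chow replicate 3, 442 without high-fat-diet replicate 2 and 75 without high-fat-diet replicate 3. Of these peaks, 199 pass in the authors' deposited table, and 177 of these also passed here, in the same direction.

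Called H3K27ac peaks overlapped the chow promoter mark less often than the other peaks did. H3K4me3 was measured in chow alone, so a promoter marked only on the high-fat diet would be missed here. Called and other peaks were not matched for signal or width. Of the 215, 47 (21.9%) overlapped a chow H3K4me3 peak, against 6510 of the 11020 others (59.1%; Fisher's exact p = 3.87e-28, two-sided, with peaks not independent). Among risen peaks the share was 24.4% and among fallen peaks 17.5%, and these shares did not pass a test of their difference (Fisher's exact p = 0.306). Without chow replicate 2, 13.5% of the called peaks overlapped, without chow replicate 3 13.6%, and without high-fat-diet replicate 2 32.6%. With an overlap of at least 50% of the peak the shares were 10.7% and 43.9%.

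At gene promoters H3K27ac rose at 39 and fell at 10 of 20891 tested, and 11 of the risen and 1 of the fallen changed over 2-fold. Promoters of the lectin gene Lgals1 and of the cyclin gene Ccnd1 rose by log2 differences of 0.63 (SE 0.0911) and 0.59 (SE 0.0914). Pparg, the fat storage regulator, rose by 0.62 (SE 0.105), Anxa2, an annexin, by 0.62 (SE 0.111) and the interferon-induced Oas3 by 1.22 (SE 0.214). Promoters of Dact2 and Susd4 fell by 0.86 (SE 0.128) and 0.83 (SE 0.126). Adjusted p values of these 7 promoters ran from 0.0053 to 0.0123. The diets did not overlap in 4074 promoters (19.5%, against 10% by chance), and 2924 had an unadjusted p below 0.05. On the first principal component of the promoters (45% of the variance) high-fat-diet replicate 1 lay at 44.89. Replicates 2 and 3 lay at −3.491 and 9.817, and the chow libraries from −21.61 to −9.923. Single libraries decided the count: without chow replicate 2 none of 21174 promoters passed in edgeR (2431 with an unadjusted p below 0.05), so each of these calls ended there, and without chow replicates 1 and 3, 1 and 7 passed. There were 95 without high-fat-diet replicate 1, 736 without replicate 2 and 8 without replicate 3. With the replicate block 470 promoters passed, 315 risen and 155 fallen, and with cyclic loess 89, 72 risen and 17 fallen. Of all promoters, 48 pass in the authors' deposited table, and 34 of these also passed here.

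As lists, promoters of blood and immune cell genes had higher H3K27ac on the high-fat diet by camera with its preset correlation, although few single promoters passed. Over all tested promoters the log2 fold change fell as promoter signal rose (Spearman's rho −0.414, as a description). Blood and immune members had a mean log2 CPM of 4.04, and members of the hepatocyte and metabolic lists set against them 6.04. These list tests do not keep signal and cell type apart. Camera called 25 lists and none with an estimated correlation, where adjusted p values began at 0.368 (fry adjusted p = 0.241 at the lowest, and 2924 single promoters had an unadjusted p below 0.05). All 17 lymphocyte marker promoters had positive log2 fold changes, with a median of 0.44 (camera adjusted p = 8.81e-06). Other lists that camera called with positive medians were class II antigen presentation, with a median of 0.86 and 7 of 7 members positive (camera adjusted p = 9.42e-09), infiltrating macrophages with 0.58 (adjusted p = 5.99e-05), and Kupffer cells with 0.35 (adjusted p = 2.54e-05). Without high-fat-diet replicate 1 these 4 medians were 0.26, 0.51, 0.36 and 0.19, and without replicate 2 the Kupffer cell median was 0.57. Interferon-stimulated genes had a median of 0.15 (adjusted p = 5.81e-05), which was 0.04 without high-fat-diet replicate 1, 0.24 without replicate 2 and 0.10 without chow replicate 3. The cytokine list had 0.27 (adjusted p = 0.00375; 0.13 without high-fat-diet replicate 3) and the cell cycle list 0.16 (adjusted p = 0.00555; 0.09 without high-fat-diet replicate 1). Calls for neutrophils (adjusted p = 0.0156) and erythroid cells (adjusted p = 0.0124) ended without high-fat-diet replicate 1 (adjusted p = 0.0577) and replicate 3 (adjusted p = 0.0508). The 7 erythroid members hold 5 distinct promoters, since Hba-a1 and Hba-a2, and Hbb-b1 and Hbb-b2, have the same counts in every library. With 1 of each identical promoter, a setting chosen after the data were seen, 24 lists passed, and the erythroid list had a median of 0.20 in place of 0.90 and did not (adjusted p = 0.115). These 4 globin genes were chosen after their values were seen. The female-biased list (adjusted p = 0.018) ended without chow replicate 1 (adjusted p = 0.0632) or high-fat-diet replicate 2 (adjusted p = 0.0721). Of single members in these lists, over all promoters 1 class II gene, 1 Kupffer cell gene and 1 female-biased gene rose. Adjusted over each list alone, 6 class II, 6 infiltrating macrophage, 6 interferon, 4 Kupffer cell and 3 neutrophil promoters rose, 1 cell cycle and 1 female-biased promoter rose, and 6 cytokine promoters rose while 1 fell. None rose among lymphocyte and erythroid promoters (edgeR). With cyclic loess, chosen for the promoter lists after the data were seen, the medians of the cytokine and cell cycle lists were 0.11 and 0.09, and both lists still passed. The neutrophil list (0.16 in place of 0.31, adjusted p = 0.0992), the female-biased list (0.16 in place of 0.30, adjusted p = 0.145) and the erythroid list (0.64, adjusted p = 0.135) did not.

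Promoter lists of hepatocyte, metabolic, insulin signaling and clock genes were called as lower in H3K27ac by camera with its preset correlation. None of them passed with an estimated correlation (lowest adjusted p = 0.368) or with fry (lowest adjusted p = 0.241). None of the 20 PPARα targets had a positive log2 fold change, with a median of −0.23 (camera adjusted p = 5.37e-06; −0.15 without high-fat-diet replicate 1). The cholesterol synthesis list had −0.23 (adjusted p = 8.81e-06), while 7 of its genes rose in mRNA, and mitochondrial oxidation had −0.15 (adjusted p = 8.81e-06). The male-biased list had −0.29 (adjusted p = 0.00102; −0.17 without chow replicate 2, −0.16 without high-fat-diet replicate 1). Apolipoproteins had −0.12 (adjusted p = 0.00016; −0.04 without high-fat-diet replicate 1, −0.22 without replicate 2) and sterol uptake −0.15 (adjusted p = 0.00298; −0.08 without replicate 1). Respiratory chain genes had −0.10 (adjusted p = 0.00912). Without high-fat-diet replicate 1 the calls ended for hepatocyte markers (adjusted p = 0.00375, then adjusted p = 0.187), gluconeogenesis (0.00117, then adjusted p = 0.134), urea and amino acids (0.00375, then adjusted p = 0.134) and drug-metabolising P450 (0.0156, then adjusted p = 0.187). They also ended there for bile acid synthesis (0.0353, then adjusted p = 0.49), insulin signaling (0.018, then adjusted p = 0.288), glutathione (0.0222, then adjusted p = 0.134) and clock genes (0.0156, then adjusted p = 0.323). Without chow replicate 3 the bile acid synthesis and insulin signaling (adjusted p = 0.0688 each), glutathione (adjusted p = 0.0516) and clock (adjusted p = 0.207) calls ended as well. Bile acid synthesis also ended without chow replicate 1 (adjusted p = 0.0796), and glutathione without high-fat-diet replicate 3 (adjusted p = 0.0846). Over all promoters 1 gene of these lists, in sterol uptake, fell. Adjusted over each list alone, 4 cholesterol, 4 apolipoprotein, 2 mitochondrial and 1 each of the PPARα, sterol uptake, gluconeogenesis, P450 and male-biased promoters fell. None fell in the hepatocyte marker, urea, bile acid synthesis, insulin, glutathione, clock and respiratory chain lists (edgeR). With cyclic loess the calls ended for sterol uptake (median −0.05, adjusted p = 0.0983), bile acid synthesis (−0.04 in place of −0.12, adjusted p = 0.209) and insulin signaling (−0.02 in place of −0.08, adjusted p = 0.605). They also ended for glutathione (−0.05 in place of −0.08, adjusted p = 0.11), clock genes (−0.01 in place of −0.08, adjusted p = 0.694) and the respiratory chain (−0.04, adjusted p = 0.442). Gluconeogenesis (−0.06 in place of −0.13), urea and amino acids (−0.10 in place of −0.15), cholesterol synthesis (−0.15), mitochondrial oxidation (−0.09) and apolipoproteins (−0.06) moved toward 0 and still passed.

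The remaining 14 promoter lists did not pass, with camera adjusted p from 0.163 to 0.963. Fatty acid synthesis had a median of −0.04, a mean of 0.04 and a test that pointed up (adjusted p = 0.963), triglyceride synthesis −0.05 (adjusted p = 0.383), lipid droplets −0.08 with a mean of 0.01 and a test that pointed down (adjusted p = 0.516), glycolysis 0.02 (adjusted p = 0.189) and bile acid transport −0.11 (adjusted p = 0.171; adjusted p = 0.0323 without high-fat-diet replicate 2). Acute-phase genes had −0.08 with a mean of 0.02 and a test that pointed down (adjusted p = 0.853), the unfolded protein response 0.003 (adjusted p = 0.365), matrix genes 0.07 with a test that pointed down (adjusted p = 0.876) and major urinary proteins −0.25 (adjusted p = 0.171). Stellate cells had 0.11 (adjusted p = 0.637), endothelial cells −0.11 (adjusted p = 0.261) and bile ducts 0.12 (adjusted p = 0.794). Adipocytes had 0.18 (adjusted p = 0.163; adjusted p = 0.0292 without high-fat-diet replicate 1) and pancreas genes 0.17 (adjusted p = 0.163; adjusted p = 0.046 without chow replicate 3). Over all promoters 1 lipid droplet gene, Pparg, and 1 glycolysis gene, the hexokinase gene Hk2, rose in these lists. Hk2 was chosen after its value of 0.91 was seen. Adjusted over each list alone, 3 acute-phase, 2 glycolysis, 2 adipocyte, 1 fatty acid synthesis, 1 triglyceride synthesis, 1 lipid droplet and 1 endothelial promoter rose, and 2 matrix, 1 lipid droplet, 1 urinary protein and 1 endothelial promoter fell. The 2 matrix promoters, Col4a1 and Col4a2, have the same counts in every library and so stand for 1 region (both chosen after their values were seen). Medians of fatty acid synthesis, triglyceride synthesis, matrix and bile duct lists changed sign with cyclic loess.

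The next comparison asks whether promoter acetylation moved with mRNA. Over 12791 genes tested in both assays, 31 promoters passed, and 13 of them (41.9%) passed in mRNA too, against 35.6% of all 12791 genes (Fisher's exact p = 0.458, two-sided, a test chosen after the data were seen). Of the 13, 11 rose in both and 2 fell in both (Fisher's exact p = 0.0128 for the direction among the 13, two-sided, with genes not independent). Lgals1 rose by a log2 of 2.92 in mRNA and 0.63 at its promoter, Ccnd1 by 2.56 and 0.59, Pparg by 0.81 and 0.62, and Oas3 by 1.85 and 1.22. The others were Anxa2 and, chosen after their values were seen, Zbp1, Gpc1, Osbpl3, Sfpi1, Cd68 and Cyp2a4, the last a female-biased gene with 2.03 and 2.35. Dact2 fell by 2.32 in mRNA and 0.86 at its promoter, and Ppp1r9a fell in both. Each promoter call ended without H3K27ac chow replicate 2, and the mRNA calls of Cd68 and Sfpi1 ended without mRNA chow replicates 1 or 2 or high-fat-diet replicate 2 (highest adjusted p = 0.077 and adjusted p = 0.0598). The mRNA change of Osbpl3 was 1.71 in place of 2.30 without high-fat-diet replicate 3.

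Promoters of the 2247 genes lowered in mRNA had a median log2 fold change of −0.10, against −0.05 for all 12791 genes and −0.003 for all 20891 tested promoters, and promoters of the 2301 raised genes had a median of −0.01 and a mean of 0.02. Against all 20891 promoters camera called the lowered genes (adjusted p = 2.76e-14; adjusted p = 0.04 with an estimated correlation) and not the raised ones, where the test pointed down (adjusted p = 0.731; adjusted p = 0.88 with an estimated correlation). Against the 12791 genes alone, a setting chosen after the data were seen, it called the lowered genes as lower (adjusted p = 9.52e-07) and the raised genes as higher (adjusted p = 0.0022). With an estimated correlation neither passed there (adjusted p = 0.14 and adjusted p = 0.225). Fry, which tests a set against no change, gave the lowered genes an adjusted p = 0.0241. Against all promoters the direction of the raised genes also turned with cyclic loess (0.03), with the strict count filter (0.006), without H3K27ac chow replicate 2 (−0.007, with the test pointing up), chow replicate 3 (0.0006) and high-fat-diet replicate 1 (0.009). Across the 12791 genes the log2 fold changes of mRNA and promoter correlated with Spearman's rho 0.24 and Pearson's r 0.21, as a description, since genes are not independent replicates. Over 901 genes changed over 2-fold in mRNA, rho was 0.35.

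**Figure D4:**
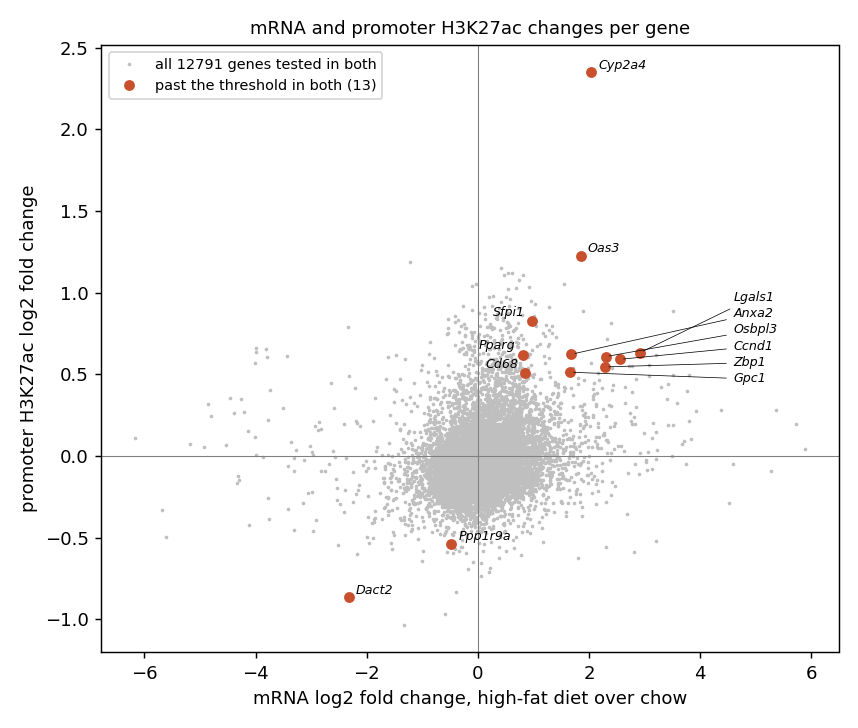
Log2 fold change in mRNA (horizontal axis) and in promoter H3K27ac (vertical axis), high-fat diet over chow, for 12791 genes, with the 13 genes past the threshold in both assays in orange. Of these, 11 lie in the upper right and 2 in the lower left.

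The H3K4me1 comparison asks where the enhancer mark differs between the diets. The peak at chromosome 5, 121144084 to 121151999, fell from 121 CPM (SD 5.94) to 70.3 CPM (SD 5.59), a log2 difference of −0.78 (SE 0.0921, adjusted p = 2.87e-05). On chromosome 17, 14308564 to 14313992 fell by 0.77 (SE 0.104), inside a region whose H3K27ac also fell. Among risen peaks, chromosome 7, 52907915 to 52910680, changed by 0.85 (SE 0.125) and chromosome 4, 138432363 to 138440458, by 0.66 (SE 0.0969). Of 16834 union peaks 263 passed, 115 risen and 148 fallen, 2 of them over 2-fold, 1 each way. With total counts the split was 142 and 133. The diets did not overlap in 3700 peaks (22.0%, against 10% by chance). The first principal component (40.4% of the variance) parted the diets, with chow from −13.96 to −5.027 and the high-fat diet from 3.477 to 21.85. On the second (29%) high-fat-diet replicate 1 lay at 23.45 and the other libraries from −6.868 to −2.599. Without chow replicates 1 to 3, 47, 34 and 65 peaks passed, and without high-fat-diet replicates 1 and 2, 2036 and 79. Of these peaks, 413 pass in the authors' deposited table, and 252 of these also passed here.

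The marks were compared where their union peaks overlapped, at 7208 of the 11235 H3K27ac peaks (64.2%). Across these peaks the log2 fold changes correlated with Spearman's rho 0.08, which was −0.05 without H3K4me1 high-fat-diet replicate 1 and 0.16 without replicate 2. At 118 overlapping peaks whose H3K27ac rose, 99 had a positive H3K4me1 log2 fold change, with a median of 0.123 over the 118. At 68 whose H3K27ac fell, 46 had a negative one, with a median of −0.11 over the 68. These shares have no test, since peaks are not independent. Peaks called in both marks numbered 17, and 15 of them moved in the same direction, such as chromosome 1, 94727530 to 94733817, with 0.84 in H3K27ac and 0.47 in H3K4me1. The 2 exceptions were a peak on chromosome 10, with −0.55 in H3K27ac and 0.51 in H3K4me1, and one on chromosome 9, with 0.43 and −0.45. These 2 were chosen after their values were seen.

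The authors' pooled peak lists, 1 per diet, were longer for chow in both marks, with 9651 against 6852 H3K27ac peaks and 15355 against 8616 H3K4me1 peaks. Their inputs differed, with 74816761 chow and 63639233 high-fat-diet tags for H3K27ac, and 93501047 and 96367524 for H3K4me1. The IgG controls had 15435587 and 12751509 tags. Peaks held 15.2% and 10.6% of the H3K27ac tags, and 18.9% and 12.1% of the H3K4me1 tags. The lowest score kept also differed, with 758.65 in chow and 1068.83 in the high-fat diet for H3K4me1. For H3K27ac it was 997.56 and 909.56. How far these inputs and cut-offs set the list lengths was not tested. Of the H3K27ac peaks, 53.3% of the chow list (95% interval 52.3 to 54.3) overlapped the high-fat-diet list and 74.99% of the high-fat-diet list (73.9 to 76.0) overlapped the chow list. For H3K4me1 the shares were 45.4% (44.7 to 46.2) and 77.5% (76.6 to 78.4). Union peaks listed in chow alone had small fold changes in the counts, with a median log2 of −0.05 for H3K27ac, where 67 of 4511 fell and 16 rose, and of −0.04 for H3K4me1, where 117 of 8378 fell and 11 rose. Those listed in the high-fat diet alone had a median of 0.07 for H3K27ac, where 78 of 1714 rose and 2 fell, and of 0.105 for H3K4me1, where 61 of 1937 rose and 5 fell. The lists have no replicates, so these shares have no test. Their intervals treat the peaks of a list as independent and leave out the spread between animals. Chow H3K4me3 gave 13065 peaks.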

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

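Values below with the pancreas covariate, those of lists with cyclic loess, and those of the mark correlation without single libraries, come from tests chosen after the results were seen. Over named genes, regions, called lists and family sums, DESeq2 size factors left 293 results with the same direction and side of the threshold. Family sums have no threshold, and were the same where the log2 ratio moved by less than the SD within diets. Counts of features and lists called are not part of this tally, nor are features without an adjusted p in a setting. With the Wald test, over named genes and regions, 232 did and 13 were no longer past it. With the replicate block, over these and lists, it was 283 and 4, and with cyclic loess, over lists alone, 28 and 13. Without chow replicates 1, 2 and 3, 237, 221 and 234 did and 56, 72 and 59 were no longer past it, and without high-fat-diet replicates 1, 2 and 3 it was 279, 265 and 254 against 14, 27 and 37. Of 28 named promoters none kept its call without each library in turn (edgeR; 2431 promoters had an unadjusted p below 0.05 without chow replicate 2), while 137 of 174 called genes did. In both union peak tables the count filters removed no peak, so those settings say nothing there. The comparison of peaks near changed genes was not run.

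With the pancreas covariate 874 mRNA genes passed in place of 4590. The covariate differs between the diets, so it can take part of a diet effect with it, and the cause of the lower count was not tested. At promoters 470 passed with the replicate block and 89 with cyclic loess in place of 49; the cause was not tested. With an estimated correlation 1 mRNA list passed in place of 16, and 0 promoter lists (limma camera) in place of 25; the cause was not tested. With 1 of each identical promoter, also chosen after the results were seen, 24 promoter lists passed, and the erythroid list was no longer past the threshold. The median for promoter H3K27ac of mRNA-raised genes, −0.01, was 0.03084 with cyclic loess and 0.005873 with the strict filter, both in the opposite direction. Against the genes of both assays, a setting chosen after the results were seen, the same median of −0.01261 tested as higher and not lower, because those genes have a median of −0.05 and all tested promoters one of −0.003. The cause of the other changes was not tested.

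Of H3K27ac chow peaks shared with high-fat diet, the share of 53.3% was 49.8% with overlap of at least 50% of each peak, 3.846% at a false discovery rate of at most 1 percent and 62.36% with lists of equal length. For H3K27ac high-fat diet peaks shared with chow 74.99% became 70.14%, 6.383% and 62.78%. For H3K4me1 chow peaks shared with high-fat diet 45.4% became 39.73%, 0.2157% and 58.8%, and for H3K4me1 high-fat diet peaks shared with chow 77.5% became 70.81%, 45.83% and 57.78%. At a false discovery rate of at most 1 percent the lists held 78 chow and 47 high-fat-diet peaks for H3K27ac and 5100 and 24 for H3K4me1, so their lengths bound these shares. The cause of the other changes was not tested.

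Without single libraries, mRNA genes called ran from 2899 (without chow replicate 2) to 5163 (high-fat-diet replicate 1), H3K27ac peaks from 44 (chow replicate 3) to 442 (high-fat-diet replicate 2) and promoters from 0 (edgeR, chow replicate 2) to 736 (high-fat-diet replicate 2). H3K4me1 peaks ran from 34 (chow replicate 2) to 2036 (high-fat-diet replicate 1) and mRNA lists from 10 (chow replicate 1) to 21 (high-fat-diet replicate 1). The median for promoter H3K27ac of mRNA-raised genes ran from −0.04062 (high-fat-diet replicate 2) to 0.00883 (high-fat-diet replicate 1). The H3K27ac and H3K4me1 fold correlation ran from −0.05102 (H3K4me1 high-fat-diet replicate 1) to 0.164 (H3K4me1 high-fat-diet replicate 2). Fewer samples lower the power of a fit, and the cause of the higher counts was not tested. In simulated data at these depths 39% of promoters planted with a log2 change of 0.5 passed, 88% of H3K27ac peaks and 68% of H3K4me1 peaks.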

Other observations

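The tests of pancreatic enzymes, of clock and feeding genes and of blood and immune cell mRNA were chosen after the results were seen, as were the rules on spread by which all tests below were read.

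Xist, which is expressed in female cells, was at or below 0.314 CPM in every mRNA library. The Y-linked Ddx3y was 104 to 119 CPM on chow and 51 to 77.9 CPM on the high-fat diet, and the Y-linked Eif2s3y 65.1 to 67.4 CPM and 40.7 to 46.9 CPM. These genes were chosen after their values were seen.

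Each comparison was repeated for the 10 splits of its 6 libraries into 3 and 3, the real one included, which are too few for a share under 0.05. Each other split has libraries of both diets on each side, so a diet difference adds to the spread within sides. The low counts of genes, promoters and peaks in these splits thus cannot show how many calls would arise without a diet difference. In mRNA the real split gave 4590 genes and the highest other 0 (edgeR), so 1 of the 10 splits gave as many. In H3K27ac 1 split gave as many peaks, with 215 in the real split and 0 in the highest other, and 1 gave as many promoters, with 49 and 0. In H3K4me1 1 split gave as many peaks, with 263 and 0. Of mRNA lists the real split called 16 and the highest other 19, and 5 splits called as many as the real one. Of promoter lists the real split called 25 and the highest other 24, so 1 split called as many. The raised-minus-lowered difference in promoter median was 0.0859 in the real split and 0.0413 in the highest other, so 1 split gave as large a value.

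Pancreatic enzyme mRNA was lower in livers of the high-fat diet, and it also varied within each diet. If pancreas tissue had been carried into some samples, its transcripts would keep 1 ratio between 2 libraries, and the SD over the 10 genes of the log2 ratio of chow replicate 1 to chow replicate 3 was 0.206 (SE 0.0486) around a median of 2.67. Other genes as abundant had an SD of 0.211 in the same ratio, so this test does not decide, and carried-over tissue stays open. The test reads the spread alone and not the shift of 2.67 that the 10 genes shared. Their mean log2 CPM ranged over 2.63 among the chow libraries. Across these genes the mean chow level correlated with the level in high-fat-diet replicate 2 at r 0.871, as a description. If the diet lowered these genes in liver cells, the high-fat-diet libraries would lie close together, and their range of mean log2 CPM was 5.37 against a difference between the diets of 5.77 (SE 1.93), which does not decide. An effect of the diet stays open.

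Clock genes and feeding-related genes both differed between the diets. Genes that peak with Arntl and genes of the opposite phase had median log2 fold changes 3.59 apart (SE 0.44), which different clock times of collection could give. Feeding-induced and fasting-induced genes had medians 3.13 apart (SE 0.491), which a different feeding state at collection could give. The labels give no clock time, and an overnight fast without its hours, so neither can be told apart from an effect of the diet itself, which stays open.

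Promoter H3K27ac was higher at blood and immune cell lists than at hepatocyte lists, by a difference of medians of 0.641 (SE 0.314; 63 and 85 promoters, with 2 pairs of globin promoters of identical counts among the 63). The former were Kupffer cell, infiltrating macrophage, lymphocyte, neutrophil, erythroid and class II lists. The latter were hepatocyte markers, PPARα targets, cholesterol synthesis, mitochondrial oxidation and apolipoproteins. Camera called each of these lists in the same promoter data, so the difference restates those calls and is not separate support. Liver lists that camera did not call, such as fatty acid synthesis with a median of −0.04, were left out. Weaker enrichment in high-fat-diet replicate 1 alone could give part of it, since the difference was 0.404 without that library, 63% of the full value (SE 49), which does not decide. The log2 fold change fell with signal over all promoters (Spearman's rho −0.414), and the blood and immune and the hepatocyte members had mean log2 CPM of 4.04 and 6.04. A trend of the fold change with promoter signal is unlikely to be the whole cause, because after cyclic loess scaling the difference was 0.502, and 78.3% (SE 8.18) of it was kept. That lies above the bound set for this test by little more than its spread, and the trend could still give part of the difference. More blood and immune cells in the livers may also raise it, and the mRNA of 41 members of the same lists had a median log2 fold change of 0.47 (SE 0.329), with 14 raised and 1 lowered. An effect of the diet on chromatin in hepatocytes was not tested apart from these.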
